A study of Mus musculus with 6 samples.

How the data were processed

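Gene expression was measured by RNA sequencing in pancreatic acinar cells of adult mice, 6 libraries in 2 groups of 3: control and cerulein. Cerulein is a cholecystokinin analogue that overstimulates acinar cells and is used to cause experimental pancreatitis. Per the labels, the mice had a CD1-enriched background and carried ElastaseCreER and a ROSA26 YFP reporter, which marks cells with a history of elastase promoter activity. Cerulein was injected 7 times on a treatment day, on alternate days over 3 days, and 1 day of recovery followed. The dose is labelled as 125 g per kg, a unit that cannot be right as written and was not used. The pancreas was digested, acinar cells were sorted by flow cytometry, and total RNA was depleted of ribosomal RNA before library preparation with a NEBNext kit. The libraries were labelled as n = 1 to n = 3 within each group. The labels do not state that each came from a different mouse, so the p-values measure the spread between these samples, which may be technical.

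The deposited table holds FPKM (fragments scaled by transcript length and by a library total) for 50660 protein-coding transcripts of 21949 genes, with 1 column per library. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the mouse build mm10, without versions. The tool that gave the deposited FPKM is not given in the sources used here. The design planned before the data were examined assumed plain FPKM or counts. The deposited values instead had lost decimal marks, as follows, so their unit was recorded as other than FPKM and the planned test for FPKM was applied to restored values.

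The deposited table had passed through a spreadsheet that read the decimal point as a mark between groups of digits. Values of 1 or more with up to 3 digits before the mark and 3 or more decimals were written as their digits in groups, so that the position of the decimal mark was lost. A value of 6 digits can then stand for 3 numbers a factor of 10 apart, and a value of 5 digits for 2. Between 18.05% and 21.4% of the transcripts of a library had no usable decimal mark. Values below 1 that needed no exponent, values with more digits before the mark, and values with at most 2 decimals were intact. Values small enough to need an exponent were taken as 0.

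The marks were restored from the structure of FPKM itself. The FPKM of a gene, times its effective length and divided by a constant of the library, is a whole number of fragments. Transcript lengths came from the GENCODE annotation of the same mouse build, which held 98.91% of the transcripts. The mean fragment length of each library and the constant were fitted on genes whose values were all intact. Of these genes, 80.6% to 83.7% lay within 0.01 fragments of a whole number, against 2% expected by chance. Candidate positions were then weighed by their distance to whole fragments and by the distance to other libraries of the same group, with a spread of 0.6 log2 units allowed between replicates. Levels were weighed within each group, while whether a gene held whole fragments was judged with values of both groups. For genes with 1 transcript the fitted length was shared by all libraries. A value was accepted at a posterior of 0.95 or more, and placements that gave totals within 5% of each other counted as the same value. The length used could differ from the annotated one by up to 600 bases, and transcripts shorter than 550 bases were not placed by fragments. Without the replicate term few values can be placed, since 10 times a whole number is also whole.

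Placement was checked on values that had kept their mark and were treated as if they had lost it. Of 390 such values 323 were placed, and 321 of these (99.4%) were placed right. At true levels of 10 to under 100, 42 of 44 were right. These genes had no other transcript with a lost mark, which makes them an easier class. On simulated data of 2421 genes, 92.4% of 5556 lost marks were placed and 99.75% of those were right. The simulated levels were drawn from genes already restored in all libraries, so these shares may not hold for the genes left open. For simulated genes with 1 replicate shifted 8-fold, only 76.3% were placed and 97.75% were right. Genes in which 1 replicate stands apart are therefore restored less often, so the tested genes lean towards those whose replicates lie close together, and p-values may be too small for that reason. The placement rule went through several versions (its prior, the treatment of transcript length, the posterior and the tolerance), chosen with the intact values and some known pancreatic genes in view, and the fit of the fragment constant was corrected after the simulation. The share placed right is for that reason not fully independent of the rule.

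Depth was read from the same structure. One FPKM of a transcript of 2000 bases stood for 6.44, 7.39 and 8.09 fragments in control libraries 1, 2 and 3 and for 23.1, 28.9 and 34.0 fragments in cerulein libraries 1, 2 and 3. A level of 0 over 2000 bases thus allows an FPKM of up to 0.465 in control library 1 and 0.0882 in cerulein library 3, taking 3 fragments as the floor. The fragments restored in all summed to 3106629, 4150236 and 3930619 in control libraries 1, 2 and 3 and to 3989363, 4601087 and 4784952 in cerulein libraries 1, 2 and 3. The base of the FPKM scale, meaning the number that takes the place of the library total, was 3501808, 4062809 and 4465618 in the control and 12706764, 16143828 and 18960149 in the cerulein libraries. In control library 2 the fragments were at least 4370174 and exceeded the base, so the base was not a plain total there. In control libraries 1, 2 and 3 the base was 1.13, 0.979 and 1.14 times the restored fragments. In cerulein libraries 1, 2 and 3 it was 3.19, 3.51 and 3.96 times those fragments. Fragments left open may account for the higher ratio in cerulein, which was not tested. A scaling that differed between the groups would shift every log2 fold change in the same direction. How the authors scaled the FPKM is not given in the sources used here. The total of fragments lay between 3274876 and 11399886 in controls and between 4570106 and 44601451 in cerulein libraries, depending on the values left open. Floors and fragments cover counting error only.

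Transcript values were summed per gene. The filter kept genes whose lowest possible FPKM was at least 1 in at least 3 libraries, which held for 8940 genes. Of these, 5985 (66.95%) were restored in all 6 libraries and tested. The other 2955 were not tested, but their bounds were compared: a gene was taken as higher or lower whatever the placement when the ranges of the groups did not overlap. Differences were tested two-sided with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, on log2(FPKM + 1), and adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on this scale, cerulein minus control, and understate the change of low genes. SE is the standard error of the log2 fold change. The smallest p of an exact permutation test of 3 against 3 is 0.1, so no permutation test per gene was used. Simulated data on the 5985 genes had 200 changed genes in each run. There limma recovered 0.295% of changes of 1.5-fold, 5.41% of 2-fold and 70.4% of 4-fold, and 3.10% of its calls were false. The simulated spread between libraries was set below the observed one before counting error was added. These shares may therefore not hold for the real data. Restoration used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

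Before the data were examined, 30 gene lists were fixed, and 20 had at least 5 tested members. They were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. Genes named in the report follow a rule fixed at the same time. It takes the 10 genes higher and the 10 lower with the largest log2 fold change among genes that passed the threshold, whose groups do not overlap and whose mean FPKM is at least 5 in the higher group, leaving out gene models without an assigned symbol. It adds up to 4 members of each list with the smallest adjusted p and a set of 9 genes given whatever their p. Genes outside the rule are said to be chosen after their values were seen. Of the 9, Ptprc and Ins2 were not restored in all libraries, and Amy2b is not analysed here. Some single genes that the rule or a count would name are not reported here. Coordinates are those of the GENCODE annotation, 1-based, on mm10. Where other protein-coding genes overlap a gene, or near-identical copies exist, its value is given as uncertain.

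The alternatives fixed in advance were a replicate block, leaving out each library in turn, and a pseudocount of 0.1. They also held no filter, a stricter filter at an FPKM of 5 and limma without the trend. Further ones were scaling by a trimmed mean of M values, scaling to the sum outside the digestive enzymes, an estimated correlation, and fry. The trimmed mean was an unweighted mean of log ratios of the restored FPKM. The enzyme list did not hold 2210010C04Rik, a trypsinogen-cluster gene model named after its values were seen, so that gene stayed in the sum. Added after seeing the data were a posterior of 0.99, a replicate spread of 1.5 log2 units, placement without the replicate term, genes restored in at least 2 libraries of each group, limma-voom on the recovered fragments, and thinning to equal fragments per FPKM.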

Results

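The transcriptome of sorted pancreatic acinar cells was compared between control mice and mice given cerulein, to describe what pancreatitis changes in these cells. There were 3 control and 3 cerulein libraries. Between 10988 and 13324 genes had an FPKM above 0 in control libraries and between 14458 and 14913 in cerulein libraries. The deposited FPKM had lost decimal marks and were restored from whole fragments, and 5985 genes could be restored in all libraries and tested. Each FPKM rested on more fragments in cerulein than in control libraries, so low levels were measured less precisely in the controls.

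**Figure D1:**
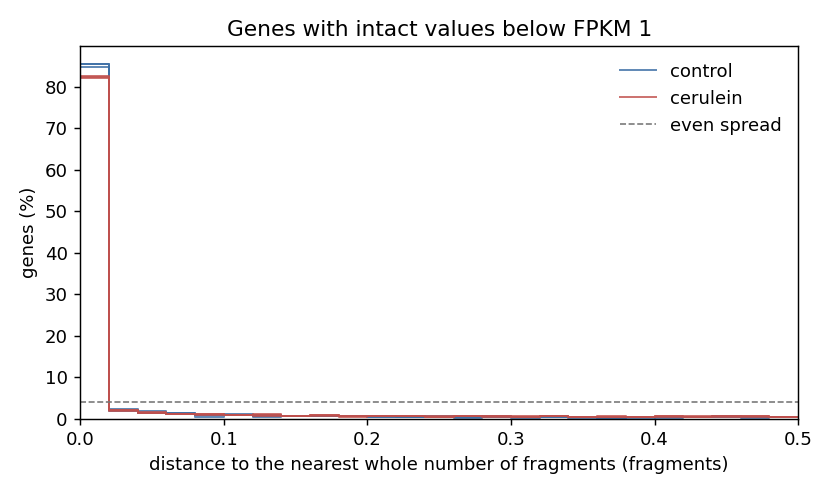
Share of genes (%, y axis) by the distance of their value to the nearest whole number of fragments (x axis, fragments), for genes whose values were all intact and below 1 FPKM, with 1 line per library coloured by group. Between 80.6% and 83.7% of genes lie within 0.01 fragments of a whole number, and the dashed line marks an even spread.

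After cerulein, many of the tested digestive enzymes, acinar genes and endoplasmic reticulum folding genes fell, while many of the tested ductal, chemokine, cell cycle, macrophage and matrix genes rose. Of the 5985 genes tested, 932 changed at an adjusted p under 0.05 by limma, 507 higher and 425 lower in cerulein, and 880 of them changed at least 2-fold. The median log2 fold change of all tested genes was 0.08. The balance of higher and lower genes moved with the scaling. When each library was scaled to the sum outside the digestive enzymes, the median moved to 0.90. Then 97.1% of the calls were higher, against 54.4% with the restored values on their deposited scale. That sum still held 2210010C04Rik, a trypsinogen-cluster gene model outside the enzyme list, named after its values were seen. It fell from 53636 to 5180 FPKM. Under that scaling 3479 genes were higher and 105 lower, and 23 of the 932 genes turned sign. Without cerulein library 2 the changed genes numbered 445, and without cerulein library 3 they numbered 403. The genes higher numbered 773 without control library 1 and 336 without control library 2.

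Most tested digestive enzymes, which acinar cells make for secretion, fell, beside a rise of macrophage markers and most tested matrix markers (list medians 2.00 and 2.96). Pancreatic triglyceride lipase, Pnlip (chromosome 19, 58652498 to 58681788), went from 42856 ± 6624 FPKM in controls to 4418 ± 789 in cerulein (SD, n = 3 each), a log2 fold change of -3.28 (SE 0.35, limma adjusted p = 7.93e-05). Carboxypeptidase A1, Cpa1 (chromosome 6, 30639218 to 30645363), went from 56782 ± 13314 to 8128 ± 2140 FPKM (log2 fold change -2.81, SE 0.38, limma adjusted p = 0.000422). Ribonuclease Rnase1, the lipase Cel and the lipase cofactor Clps fell, with log2 fold changes of -3.35, -3.25 and -2.84, and the elastase Cela2a, which overlaps other genes and is uncertain, had one of -2.98. Of 23 tested enzymes 16 fell, 1 rose and 6 did not pass, with a median of -1.89, or -0.68 when scaled to the sum outside the enzymes. Adjusted over the list alone, 18 fell and 1 rose. The list was lower than other genes by camera (adjusted p = 1.69e-10), with adjusted p = 0.164 with an estimated correlation. The enzyme that rose was Prss3, named after its value was seen, a trypsinogen with near-identical copies, at 572 ± 103 FPKM in controls and 2783 ± 458 in cerulein. The amylase gene copies were uncertain, because Amy2a1, also named after its values were seen, was listed at 0 in control library 3 and at 11777 and 13813 FPKM in control libraries 1 and 2. Amy2a5 fell (log2 fold change -3.30, limma adjusted p = 0.00185). The tested enzymes with a fragment count took 63.4%, 55.7% and 62.0% of the restored fragments in control libraries 1, 2 and 3 and 44.7%, 38.8% and 31.2% in cerulein libraries 1, 2 and 3. An enzyme without a fragment count in a library, such as Clps in at least 1, could not enter the share there. The same enzyme fragments were 56.3%, 56.9% and 54.6% of the base of the FPKM scale in controls and 14.02%, 11.1% and 7.87% in cerulein. That base was not a plain total of fragments in control library 2. It was also 3.19 to 3.96 times the restored fragments in cerulein libraries, against 0.979 to 1.14 times in controls.

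Genes of acinar identity fell in part, in libraries in which markers of macrophages (list median 2.00) and most tested markers of matrix (2.96) rose. The transcription factor Bhlha15 (Mist1), which maintains the secretory architecture of acinar cells (chromosome 5, 144190286 to 144194441), went from 73.8 ± 20.7 to 8.57 ± 6.02 FPKM (SD, n = 3 each; log2 fold change -3.11, SE 0.41, limma adjusted p = 0.000358). Ptf1a, the acinar lineage factor (chromosome 2, 19445663 to 19447501), went from 44.3 ± 14.4 to 11.5 ± 2.5 FPKM (log2 fold change -1.83, SE 0.33, limma adjusted p = 0.00299). When scaled to the sum outside the enzymes, Ptf1a had an adjusted p of 0.0819, within a range over alternatives of 0.00064 to 0.0819. The gap junction gene Gjb1, the zymogen granule glycoprotein Gp2 and the aquaporin Aqp12 fell, with log2 fold changes of -2.71, -2.62 and -2.54. Of 21 tested members 11 fell and 10 did not pass, with a median of -1.45, or -0.32 when scaled to the sum outside the enzymes, and adjusted over the list alone 13 fell. The list was lower by camera (adjusted p = 4.86e-08), with adjusted p = 0.164 with an estimated correlation.

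**Figure D2:**
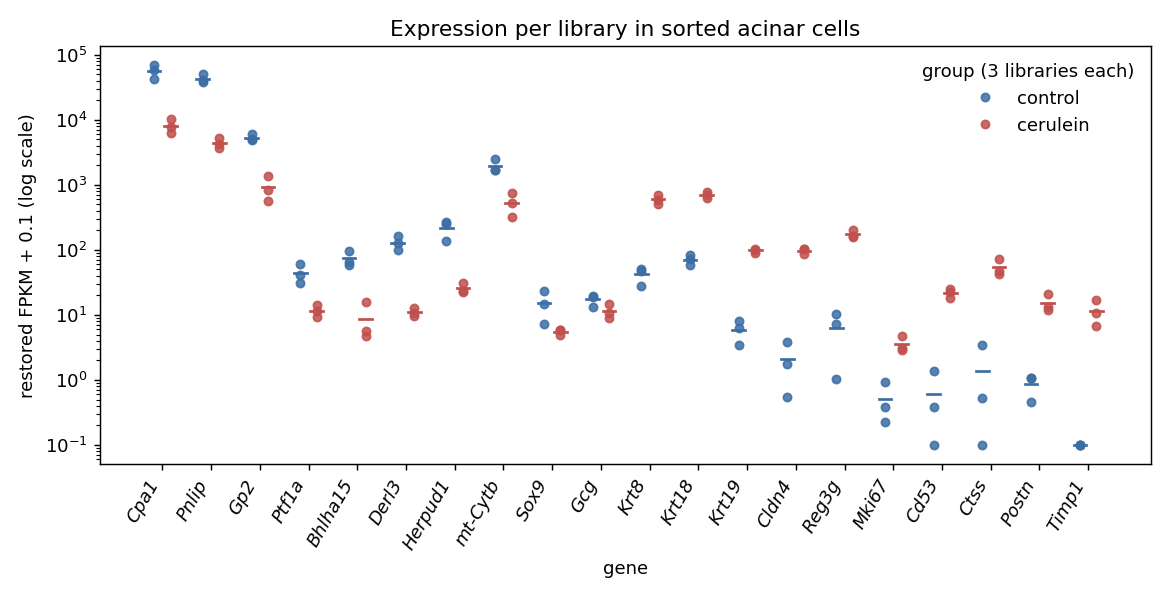
Restored FPKM plus 0.1 (y axis, log scale) of 20 genes (x axis) in each of the 3 control and 3 cerulein libraries, where a point is 1 library and a bar the mean of the group. Cpa1 and Pnlip lie lower in every cerulein library than in any control library and Krt8, Krt19 and Cldn4 higher, while the groups overlap for Gcg.

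Most tested genes of protein folding in the endoplasmic reticulum fell, while macrophage markers and most tested matrix markers rose (list medians 2.00 and 2.96). Derl3, a component of the degradation of misfolded proteins (chromosome 10, 75893413 to 75895941), went from 129.8 ± 31.6 to 10.95 ± 1.55 FPKM (SD, n = 3 each; log2 fold change -3.43, SE 0.31, limma adjusted p = 2.29e-05). Herpud1 went from 218.2 ± 71.9 to 25.5 ± 4.79 FPKM (limma adjusted p = 0.000152). Edem1 and Sdf2l1 fell, with log2 fold changes of -2.60 and -2.08, the last at an adjusted p of 0.0637 when scaled to the sum outside the enzymes (range over alternatives 0.00064 to 0.0637). Of 14 tested members 10 fell and 4 did not pass, with a median of -1.84, or -0.66 when scaled to the sum outside the enzymes, and adjusted over the list alone 10 fell. A further 15 members were not restored, their direction left open. The list was lower by camera (adjusted p = 5.11e-09), with adjusted p = 0.164 with an estimated correlation. Creb3l1, a transcription factor of secretory capacity outside the list, fell by 3.24 on the log2 scale. The integrated stress response list was not called (camera adjusted p = 0.519): Fgf21, Aldh1l2 (overlapping another gene) and Stc2 were among 3 members that fell, and Trib3 was among 2 that rose, with the same counts adjusted over the list alone. Stc2 did not pass without cerulein library 2, without cerulein library 3 or when scaled to the sum outside the enzymes, and neither Stc2 nor Trib3 passed with no filter.

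Epithelial genes that are typical of ducts and of acinar-to-ductal metaplasia, the change of acinar cells towards a duct-like state, rose in part. Macrophage markers and most tested matrix markers also rose in these libraries (list medians 2.00 and 2.96). Krt19, a keratin of duct cells (chromosome 11, 100140810 to 100148665), went from 5.84 ± 2.29 to 98.5 ± 7.62 FPKM (SD, n = 3 each; log2 fold change 3.92, SE 0.33, limma adjusted p = 1.46e-05). The tight junction gene Cldn4 (chromosome 5, 134945119 to 134946934) went from 1.96 ± 1.69 to 97.7 ± 8.64 FPKM (log2 fold change 5.22, SE 0.40, limma adjusted p = 5.09e-06). Krt8 and Krt18, keratins of simple epithelia, rose by 3.83 and 3.30 on the log2 scale. Sox9, a ductal transcription factor (chromosome 11, 112782224 to 112787760), had 14.9 ± 7.91 FPKM in controls and 5.41 ± 0.547 in cerulein, a log2 fold change of -1.18 (SE 0.38) that did not pass at an adjusted p of 0.05001. It passed in 7 of 16 alternatives, and over the 16 its adjusted p ranged from 0.0108 to 0.804. Of 15 tested members 9 rose, 1 fell and 5 did not pass, with a median of 1.66. Adjusted over the list alone, 9 rose and 3 fell. The list was higher by camera (adjusted p = 0.000101), with adjusted p = 0.164 with an estimated correlation, and was not called at a replicate spread of 1.5 either. Of the gastric and mucin list only 2 members were tested: Tff2, a trefoil peptide, fell by 3.25 on the log2 scale, and Gkn3, at 0 in every control library, was at least 3.99-fold higher. The tuft cell list had 1 tested member, Plcg2, which rose by 1.36 on the log2 scale; it did not pass without cerulein library 2, without cerulein library 3 or with no filter.

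**Figure D3:**
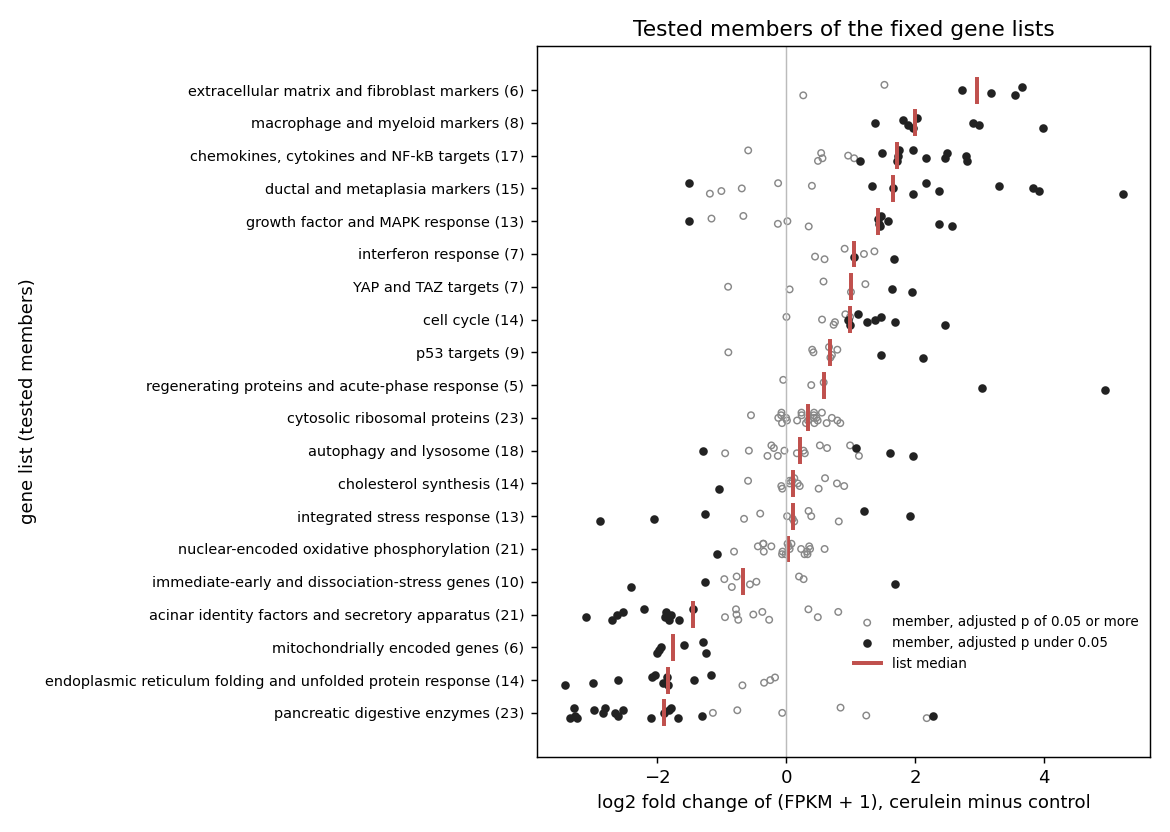
Log2 fold change of FPKM + 1, cerulein minus control (x axis), of the tested members of each gene list (y axis, number of members in brackets), where filled points passed an adjusted p of 0.05, open points did not and red bars are list medians. The medians of the digestive enzyme, folding, mitochondrially encoded and acinar lists lie at -1.89, -1.84, -1.76 and -1.45, and those of the matrix and macrophage lists at 2.96 and 2.00.

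Some injury-associated and inflammatory genes rose, in the same libraries in which 8 of 8 tested macrophage markers (median log2 fold change 2.00) and 4 of 6 matrix markers (2.96) rose. The antimicrobial lectin Reg3g (chromosome 6, 78466269 to 78468872) went from 6.13 ± 4.79 to 173.6 ± 27.2 FPKM (SD, n = 3 each; log2 fold change 4.95, SE 0.52, limma adjusted p = 7.45e-05), and Il1rn, an antagonist of interleukin-1, rose by 3.04 on the log2 scale. Of 5 tested regenerating and acute-phase genes 2 rose and 3 did not pass, with a median of 0.58, or 1.60 when scaled to the sum outside the enzymes, and the same counts adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.188 with an estimated correlation). Reg1, named after its values were seen, could not be restored. Of the 9 members of this list that were not restored, 1 was higher whatever the placement. The chemokines Ccl7, Cxcl1, Cxcl17 and Cxcl16, the last overlapping another gene, rose by 2.81, 2.79, 2.47 and 2.50. Of 17 tested chemokines, cytokines and NF-kB targets 11 rose and 6 did not pass, with a median of 1.72, and adjusted over the list alone 11 rose (camera adjusted p = 1.19e-07, and adjusted p = 0.205 with an estimated correlation), a list also not called when placed without the replicate term. Of 7 interferon-response genes Psmb8 and Ddx58 rose and 5 did not pass, with a median of 1.059, or 1.69 when scaled to the sum outside the enzymes, and adjusted over the list alone 3 rose. That list was called by camera (adjusted p = 0.0115) but not with an estimated correlation (adjusted p = 0.410), by fry (0.141), without cerulein library 2 or when scaled to the sum outside the enzymes. Psmb8 did not pass without cerulein library 2, Ddx58 did not pass without control library 2 or 3 or cerulein library 2 or 3, neither passed with no filter, and Ddx58 did not pass at a replicate spread of 1.5.

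Some proliferation and growth-factor genes rose, again beside macrophage markers and most tested matrix markers (list medians 2.00 and 2.96). Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), went from 0.409 ± 0.361 to 3.51 ± 1.02 FPKM (SD, n = 3 each; log2 fold change 1.69, SE 0.31, limma adjusted p = 0.00341). The replication helicase gene Mcm6 rose by 2.47 on the log2 scale, Top2a by 1.38 and Ube2c, which overlaps another gene, by 1.47. Neither Top2a nor Ube2c passed without cerulein library 3, and Ube2c did not pass with no filter, by limma-voom or after thinning. Of 14 tested cell cycle genes 8 rose and 6 did not pass, with a median of 0.99, or 1.57 when scaled to the sum outside the enzymes, and adjusted over the list alone 11 rose (camera adjusted p = 5.86e-06, and adjusted p = 0.164 with an estimated correlation). In the growth factor and MAPK list Fosl1 (overlapping another gene), Lif, Epha2 and Dusp4 rose by 2.57, 2.37, 1.59 and 1.42. Of its 13 tested members 7 rose, 1 fell and 5 did not pass, with a median of 1.42. The member that fell was Spry1, named after its value was seen, an inhibitor of the same pathway. Adjusted over the list alone, 7 rose and 2 fell. The list was called by camera (adjusted p = 0.0154) but not with an estimated correlation (adjusted p = 0.378), without control library 3, at a replicate spread of 1.5 or when scaled to the sum outside the enzymes. Of 9 tested p53 targets Phlda3 and Psrc1 rose and 7 did not pass, with a median of 0.69, or 1.85 when scaled to the sum outside the enzymes. Adjusted over the list alone, 2 rose and 1 fell. The list was called by camera (adjusted p = 0.0350) but not with an estimated correlation (adjusted p = 0.236), without control library 1, without cerulein library 1, with the stricter filter, at a posterior of 0.99 or by limma-voom. Psrc1 did not pass without control library 1 or 3, without cerulein library 1 or 2, with a pseudocount of 0.1, with no filter or at a replicate spread of 1.5. The YAP and TAZ list was not called (camera adjusted p = 0.0783), but was called without control library 1 (0.0118), without cerulein library 2 (0.0498) and with no filter (0.0408). Its members Cyr61 and Gadd45b rose by 1.96 and 1.65, and the other 5 did not pass, while adjusted over the list alone 3 rose and 1 fell.

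Markers of other cell types that a sorted library can hold moved with cerulein. The leukocyte gene Cd53 (chromosome 3, 106759921 to 106790149) went from 0.517 ± 0.662 to 21.8 ± 3.53 FPKM (SD, n = 3 each; log2 fold change 3.98, SE 0.35, limma adjusted p = 1.71e-05). Cd14, Coro1a (overlapping another gene) and the macrophage receptor Mrc1 rose by 2.99, 2.91 and 1.81, the last not with no filter. The 8 tested macrophage and myeloid members rose, also adjusted over the list alone, with a median of 2.00 (camera adjusted p = 1.19e-07, and adjusted p = 0.205 with an estimated correlation). The list had 11 further members above the filter that were not restored, 4 of them higher whatever the placement, among them Ptprc (CD45), at least 2.92-fold higher between the nearest libraries. The cathepsin gene Ctss, the single tested member of the MHC class II list, rose by 4.87. Of 6 tested matrix and fibroblast members 4 rose and 2 did not pass, with a median of 2.96, and adjusted over the list alone 4 rose (camera adjusted p = 7.66e-05, and adjusted p = 0.205 with an estimated correlation). Periostin, Postn, went from 0.771 ± 0.356 to 15.4 ± 5.14 FPKM and Fbn1 (overlapping another gene) from 0.770 ± 0.648 to 10.6 ± 3.60. Timp1, which overlaps another gene and was at 0 in every control library, was at least 9.84-fold higher. Control library 1 stood apart. It held 25.5 FPKM of the collagen gene Col1a2 against 0.0476 and 0.260 in control libraries 2 and 3, and 14.3 FPKM of the endothelial gene Eng against 0 in both. The 2 matrix members that did not pass were Pdgfrb and Col5a1, named after their values were seen. Control library 1 held 7.29 and 11.3 FPKM of them, above every cerulein library (at most 2.21 and 7.52). Col1a2 rose by 3.66 on the log2 scale but did not pass without control library 2, without control library 3, without cerulein library 1, with no filter or at a replicate spread of 1.5. Over the alternatives its log2 fold change ranged from 2.84 to 5.87 and its limma adjusted p from 6.12e-06 to 0.127. Of the 17 matrix members left open, 14 were open in control library 1, and 10 of these in that library alone.

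Eng, which overlaps another gene, was the single tested endothelial member and did not pass (adjusted p = 0.715), except without control library 1 (adjusted p = 0.00108, with a range over alternatives of 0.00108 to 0.920). The glucagon gene Gcg, the single tested islet member, had 17.3 ± 3.57 FPKM in controls and 11.4 ± 3.01 in cerulein (SD, n = 3 each) and did not pass (limma adjusted p = 0.252). Its log2 fold change was -0.56, and 0.56 when scaled to the sum outside the enzymes. The insulin gene Ins2 was not restored and its direction stayed open. No member of the neutrophil, lymphocyte, erythroid, adipocyte or mesothelial lists was above the filter.

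The 6 tested mitochondrially encoded transcripts fell, and 7 further ones were not restored, their direction left open. Macrophage markers and most tested matrix markers rose in the same libraries (list medians 2.00 and 2.96). The cytochrome b gene mt-Cytb went from 1971 ± 468 to 533 ± 210 FPKM (SD, n = 3 each; log2 fold change -1.94, SE 0.37, limma adjusted p = 0.00434), and mt-Nd5, mt-Nd4 and mt-Nd2 fell, with log2 fold changes of -2.00, -1.97 and -1.58. Of these mt-Nd5 and mt-Nd4 overlap other genes. They fell also adjusted over the list alone, with a median of -1.76 (camera adjusted p = 1.47e-05, and adjusted p = 0.222 with an estimated correlation). When scaled to the sum outside the enzymes the median was -0.55 and these 4 genes did not pass, mt-Nd2 also without cerulein library 2 and with no filter. Nuclear-encoded oxidative phosphorylation was not called (camera adjusted p = 0.519): of 21 tested members 1, Ndufs7, fell (log2 fold change -1.08), with a value of 0.05 when scaled to the sum outside the enzymes. Ndufs7 did not pass without control library 2 or without any 1 of the cerulein libraries, and adjusted over the list alone no member passed, with 2 at an unadjusted p under 0.05. Cytosolic ribosomal proteins were not called either (camera adjusted p = 0.270), except without control library 3 (0.00643) and when scaled to the sum outside the enzymes (0.0184), and by limma none of 23 tested members passed, also adjusted over the list alone (1 at an unadjusted p under 0.05), with log2 fold changes of 0.43 for Rps4x and 0.63 for Rps6. Both passed when scaled to the sum outside the enzymes, and Rps6 also without control library 3. A further 56 ribosomal protein genes and 22 genes of nuclear-encoded oxidative phosphorylation were above the filter but not restored, so they were not tested. Cholesterol synthesis was not called (camera adjusted p = 0.772), with 1 of 14 members, Dhcr7, lower. Dhcr7 did not pass without control library 2, without any 1 of the cerulein libraries, with no filter, after thinning or when scaled to the sum outside the enzymes, and by limma adjusted over the list alone no member passed (2 at an unadjusted p under 0.05). Autophagy and lysosome genes were not called by camera (adjusted p = 0.383), while fry gave an adjusted p of 0.0143. Of 18 tested members 3 rose, among them Ctsl and Npc2, 1 fell, Neu1, and 14 did not pass, and adjusted over the list alone 4 rose and 1 fell. Neither Npc2 nor Neu1 passed without cerulein library 2, without cerulein library 3 or with no filter, Npc2 also not without control library 2 or cerulein library 1, and Neu1 also not when scaled to the sum outside the enzymes.

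Immediate-early and dissociation-stress genes, which respond within minutes to tissue handling, had a median of -0.67, or 0.52 when scaled to the sum outside the enzymes. In the same libraries macrophage markers and most tested matrix markers rose (list medians 2.00 and 2.96). Fosb and Fos fell, with log2 fold changes of -2.41 and -1.26, Ier5 rose by 1.69, and 7 of 10 members did not pass. Adjusted over the list alone, 5 fell and 1 rose. Neither Fos nor Ier5 passed with no filter, and Fos did not pass without cerulein library 1, 2 or 3 or when scaled to the sum outside the enzymes. The list was called by camera (adjusted p = 0.0350) but not with an estimated correlation (adjusted p = 0.267), without control library 1, without control library 3, without cerulein library 1, with the stricter filter, at a posterior of 0.99, at a replicate spread of 1.5 or when scaled to the sum outside the enzymes.

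Several of the largest changes lay outside the lists. Sprr1a, an epithelial cornified envelope gene (chromosome 3, 92483952 to 92485895), was at 0 in every control library and at 57.1 ± 8.19 FPKM in cerulein (SD, n = 3), at least 45.4-fold higher than the floor of 3 fragments per control library (limma adjusted p = 1.01e-07). The tachykinin precursor gene Tac1 (chromosome 6, 7554879 to 7565834) was likewise at 0 in the controls and at 20.1 ± 5.49 FPKM in cerulein, at least 22.5-fold higher (limma adjusted p = 2.61e-06). The actin-severing gene Dstn rose from 33.0 ± 17.4 to 485 ± 97.0 FPKM. Mrps6 rose by 4.94 on the log2 scale but overlaps Slc5a3, so its value is uncertain. C2cd4b (chromosome 9, 67759437 to 67760930) fell from 27.5 ± 8.10 to 0.380 ± 0.0861 FPKM (limma adjusted p = 3.59e-06). The transcription factor Klf15 (chromosome 6, 90462576 to 90475238) fell from 26.7 ± 5.54 to 0.834 ± 0.284 FPKM (limma adjusted p = 6.34e-06), and Sostdc1, a secreted inhibitor of BMP signalling, fell by 3.77 on the log2 scale.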

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

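Scaling, library choice and the placement of decimal marks moved the counts, and the placement settings were chosen after seeing the data. Among the main calls that each setting tested, from 83 without the replicate term to all 932, none turned sign under a setting other than scaling to the sum outside the digestive enzymes, where 23 did. There Ndufs7 went to 0.0538 (range of its adjusted p over alternatives 0.00822 to 0.877). Under that scaling 3584 genes changed, 3479 higher and 105 lower, and 2675 at least 2-fold, with the median of all genes shifted to 0.898. Leaving out 1 library gave 403 to 1388 changed genes, 232 to 773 higher, 171 to 615 lower, 403 to 1148 at least 2-fold, and 12 to 14 lists. The lowest gene counts came without cerulein library 3 and the highest without control library 1, while the 12 lists came without cerulein library 1. With no filter (12926 genes) 488 changed, 285 higher and 203 lower, 418 at least 2-fold. With the stricter filter (1837 genes) 599 changed, 246 of them higher, 523 at least 2-fold, and 8 lists were called of 14 that could be tested.

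Placement at a posterior of 0.99 left 4924 genes and 9 lists called of 16. With a replicate spread of 1.5 log2 units 3388 genes were left, of which 389 changed (202 higher, 187 lower, 370 at least 2-fold) and 8 lists of 16 were called; 379 of the 486 main calls tested there were kept. Without the replicate term 704 genes were left, of which 59 changed (33 higher, 26 lower, 59 at least 2-fold) and 2 lists of 4 were called. Among the genes shared with the main placement, 4924, 3246 and 703, none was placed otherwise. For the posterior of 0.99 this was fixed in advance, since that setting only raised the cut-off for accepting a placement. Fewer genes tested explains part of these drops; the rest of the cause was not tested. With an estimated correlation camera called 0 of 20 lists (5 at an unadjusted p under 0.05), against 14 with the preset one and 14 by fry. Of the 77 named genes past the threshold, 55 kept their call under every alternative that tested them.

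Whether the replicate numbers paired the samples could not be told. The correlations of same-numbered libraries were 0.175, 0.147 and -0.0376. Control libraries 1 and 2 correlated best with their own number, and control library 3 did not. With the replicate number as a block 1028 genes changed, 550 higher and 478 lower, 968 at least 2-fold, and 14 lists were called. The pseudocount, the trimmed mean scaling (453 higher, 474 lower), limma without the trend, limma-voom on 5557 genes (1036 changed) and thinning (871 changed) kept each count within 1.5 times the main one. Genes restored in at least 2 libraries of each group gave 1328 changes among 6937 tested. In the simulated test, with 200 of 5985 genes changed per run, 5.41% of changes of 2-fold were recovered. With so few genes changed, an adjusted p is harder to pass than in the real data, where 932 genes passed. The share therefore does not give what was detectable here, and changes near 2-fold may still have been missed.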

Other observations

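The genes in this paragraph were chosen after their values were seen. In the trypsinogen cluster on chromosome 6, gene models moved in opposite directions. 1810009J06Rik (40964754 to 40968435) was at 1.58, 1.054 and 1.61 FPKM in control libraries 1, 2 and 3 and at 505, 1454 and 932 in cerulein libraries 1, 2 and 3 (limma adjusted p = 6.57e-08). Gm2663 was at 0.407, 6.51 and 0.997 against 861, 1666 and 1487 FPKM (adjusted p = 5.65e-07), and Gm10334 rose by 1.54 on the log2 scale. The neighbouring 2210010C04Rik fell from 53636 ± 20688 to 5180 ± 615 FPKM (SD, n = 3 each; limma adjusted p = 0.000154), and Prss2 from 40054 ± 6884 to 11520 ± 2624. Try5 had a log2 fold change of -0.06 (adjusted p = 0.933). These genes have near-identical copies between which reads can be split, so each value is uncertain, and no test of single copies was run.

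The genes in this paragraph, too, were chosen after their values were seen, from no list and with no test of a group. Tropomyosin 4, Tpm4, went from 3.45 ± 1.52 to 57.2 ± 8.32 FPKM (SD, n = 3 each; limma adjusted p = 1.71e-05), annexin A2, Anxa2, from 2.08 ± 1.23 to 36.4 ± 11.9, and the non-muscle myosin gene Myh9 from 10.7 ± 5.47 to 53.1 ± 6.54. Klb, the co-receptor of the hormone that Fgf21 encodes, fell from 8.59 ± 2.15 to 0.480 ± 0.302 FPKM, as Fgf21 itself fell from 24.96 ± 5.47 to 2.60 ± 1.12.

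In the next paragraphs the tests of fragments per FPKM and of a lower acinar share were written after the results were seen, and the others before. More genes were higher (507) than lower (425) in cerulein. Scaling to the sum outside the enzymes tested whether their large share of fragments set this balance. If so, no clear majority of higher calls was predicted, and if not, a clear majority. The share of higher calls moved to 97.07%. But the sum still held 2210010C04Rik, which fell from 53636 to 5180 FPKM, and lacked genes not restored in all libraries. The base of the FPKM scale was also not a plain total in control library 2, where at least 4370174 fragments exceeded the base of 4062809. The test therefore cannot decide, and this explanation stays open. Thinning every library to equal fragments per FPKM left 453 genes higher and 418 lower, an excess of 35 against 82 before, so the greater number of fragments behind each FPKM in cerulein stays open as part of the balance. With trimmed mean scaling 48.9% of calls were higher, and an effect of cerulein on the balance was not shown.

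Macrophage markers and most tested matrix markers were higher in cerulein although acinar cells had been sorted. A lower share of acinar cells, with an unchanged mix of the other types, would raise the markers of those types alike. But over members restored in at least 2 libraries of each group the macrophage median lay 2.93 log2 units above the islet median (12 and 5 members). Iapp and Ttr, named after their values were seen, fell. These values bear only on an unchanged mix, and a lower acinar share with a changed mix was not tested. Macrophage cells or RNA carried through the sort would raise their genes together, but that 100% of the tested macrophage members were higher restates the pattern, so that source and expression by acinar cells themselves after cerulein both stay open. Placement favours genes whose replicates lie close together, so members left open could differ, and 4 of 11 of these were higher whatever the placement. Expression by acinar cells was not tested, nor was the source of the 25.5 FPKM of Col1a2 and 14.3 of Eng in control library 1.

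The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 932 changed genes (507 higher, 425 lower, 880 at least 2-fold) and 14 lists, and it was the 1 split with results as large. The highest of the other splits gave 0 genes by limma, at most 283 at an unadjusted p under 0.05 against 1796 in the real split, and 11 lists. All splits used values whose decimal marks had been placed within the real groups, with replicates weighed to lie close together. That favoured the real split in advance, by an amount that was not tested.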
